A study of Mus musculus with 6 samples.

How the data were processed

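RNA-seq was carried out on C2C12 mouse myoblasts after 3 days in differentiation medium, with 3 Ctrl-gRNA and 3 Prr33-gRNA libraries. Per the labels, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit, and the second group had been made by CRISPR/Cas9 as a Prr33 knockdown line. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries of a group came from separate cultures or separately derived lines, so the p-values measure the spread between these libraries, which may be technical. Library pairs within a group differed by more than counting noise (chi-square per gene 2.90 to 5.71), so no library was counted as a duplicate.

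Gene counts were deposited by the authors as whole reads per gene, not normalized. Per the submitters' processing notes, the tools were CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3, with the mm10 build. The notes as used here state no role, strand setting or annotation release. Reads that overlap a gene on the other strand can therefore not be told apart from that gene's own. The table has 55804 rows, of which 55471 carry an Ensembl gene ID. Of these, 55230 were found in GENCODE M21 (GRCm38), and 99.5% of those had the same start and end. The other 333 rows are marked as new gene models and took 0.201% ± 0.00297 (SD, n = 3) of counts in Ctrl-gRNA and 0.251% ± 0.00176 (SD, n = 3) in Prr33-gRNA. They name genomic loci, so they stayed in the library sizes and tests. A second table of FPKM values per gene was deposited by the authors. Each FPKM column equals counts over gene length and 1 constant, which was 0.973 to 0.978 of the library's total in Ctrl-gRNA and 1.03 to 1.04 in Prr33-gRNA, and the sources used here do not state how it was set. The TMM factors computed here from the counts were close to it, at 0.969 to 0.971 in Ctrl-gRNA and 1.03 to 1.04 in Prr33-gRNA. Tests on FPKM are therefore not a separate check on the scaling. FPKM was used only for the values of Prr33 and for alternative tests.

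Total counts were 19118010, 17006381 and 17342403 in the Ctrl-gRNA libraries and 17928559, 17412383 and 19471762 in the Prr33-gRNA libraries. With TMM-scaled library sizes, 3 counts in a library correspond to 0.150 to 0.182 CPM. Intervals and floors given in the text cover counting error only, since reads without molecular identifiers are not independent molecules.

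The counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust fitting) in R 4.3.3, after filterByExpr and TMM scaling, with 2 groups and no covariate. This kept 14651 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. On counts simulated from the same means and library sizes, with 50 genes changed at each fold among 14425 tested, edgeR recovered 25 at 1.25-fold, 32 at 1.5-fold, 39 at 2-fold and 49 at 4-fold, with 15 false calls.

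Before the data were examined, 34 gene lists were fixed for muscle programmes, the cell cycle, matrix, signalling, stress, metabolism, RNA quality and markers of other cell types. The 33 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over the lists. Camera compares a list with the other genes. A few genes belong to more than 1 list. The named genes were also set by a rule: Prr33; the 10 protein-coding genes with the highest rise and the 10 with the deepest fall, clone-named genes such as those with Gm and Rik symbols left out, among those past the threshold, averaging at least 5 CPM and with no overlap between groups; up to 4 members per list with the lowest adjusted p, or abundant members where few passed; 12 fixed myogenic and cell-cycle genes; and tested genes within 200 kb of Prr33. Genes named outside this rule are said to be so, or are given for their overlap or as similar copies. Where a gene had 0 counts in a group, its fold is a bound against 3 counts over that group.

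Alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of at least 1 CPM in 3 libraries, protein-coding genes only, a replicate block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), leaving out each library, an adjusted p below 0.01, an absolute log2 fold change of at least 1, camera with an estimated correlation, and fry. Library size without scaling factors, leaving out rows with no Ensembl ID or on patch scaffolds, and leaving out chromosome 14 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.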

Results

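RNA was sequenced from C2C12 cells, a mouse myoblast line that leaves the cell cycle and fuses into myotubes when serum is lowered. The cells carried either a control guide RNA (Ctrl-gRNA) or a CRISPR/Cas9 guide RNA against Prr33 (Prr33-gRNA), and were collected after 3 days in differentiation medium. Each group had 3 libraries. Total counts per library ran from 17006381 to 19118010 in the Ctrl-gRNA group and from 17412383 to 19471762 in the Prr33-gRNA group. The comparison asks how gene expression in differentiating myoblasts differs between the control line and the line in which Prr33 was targeted. The labels do not name more than 1 line per guide. For no result below can an effect of the guide be told apart from a difference between derived lines. Expression levels below are mean ± SD of CPM (counts scaled to library size) over the 3 libraries of a group, and fold changes are log2 values of Prr33-gRNA minus Ctrl-gRNA.

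Prr33 transcript was lower in the Prr33-gRNA libraries. The counts were 1137, 990 and 913 in the Ctrl-gRNA libraries and 793, 829 and 848 in the Prr33-gRNA libraries, and the level was 58.6 ± 3.76 CPM against 43.8 ± 1.82 CPM. The log2 fold change was -0.42 (SE 0.06; edgeR adjusted p = 1.37e-06). In the deposited FPKM values the means were 23.1 ± 1.42 and 17.4 ± 0.757. Prr33 (ENSMUSG00000043795) lies on the minus strand of chromosome 7 at 142491074 to 142506771 (mm10). Its gene body overlaps the plus-strand genes Lsp1 (142460809 to 142494867) and Tnnt3 (142498836 to 142516009), but 0 of its 2348 exonic bases in GENCODE M21 overlap an exon of either. The count table gives Prr33 a length of 2514 and calls it protein-coding, where GENCODE M21 has a long intergenic noncoding RNA, so the exons that were counted may differ. The sources used here give no strand setting for counting, so reads from unspliced Lsp1 or Tnnt3 RNA over Prr33 exons would count for Prr33. The guide sequence is not given in the sources used here, so the edited position within the gene is not stated, and counts per gene do not show the edit.

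Of the 12 tested genes within 200 kb of Prr33, 9 were lower and 3 did not pass the test. Tnnt3 and Tnni2, which encode fast-muscle troponins, fell (log2 fold changes of -0.70 and -0.75). Lsp1, the imprinted RNA H19 and the muscle-expressed RNA Nctc1 had log2 fold changes of -0.69, -0.57 and -0.84. Syt8, Ifitm10 and Ins2, each below 10 CPM in the Ctrl-gRNA libraries, had values of -0.97, -1.61 and -1.34. Igf2os had -3.76 (-4.35 without Prr33-gRNA replicate 3), but it overlaps Igf2 and the readthrough gene Gm49394, each with at most 5 counts in any library. Reads over these 3 genes may have been split or discarded in counting, so the level of Igf2 cannot be read from the table and that of Igf2os is uncertain. Ctsd (0.04), Mrpl23 (-0.07) and Gm33148 (0.08) did not pass, although Ctsd was called higher, at 0.13, when libraries were scaled by their size alone.

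**Figure D1:**
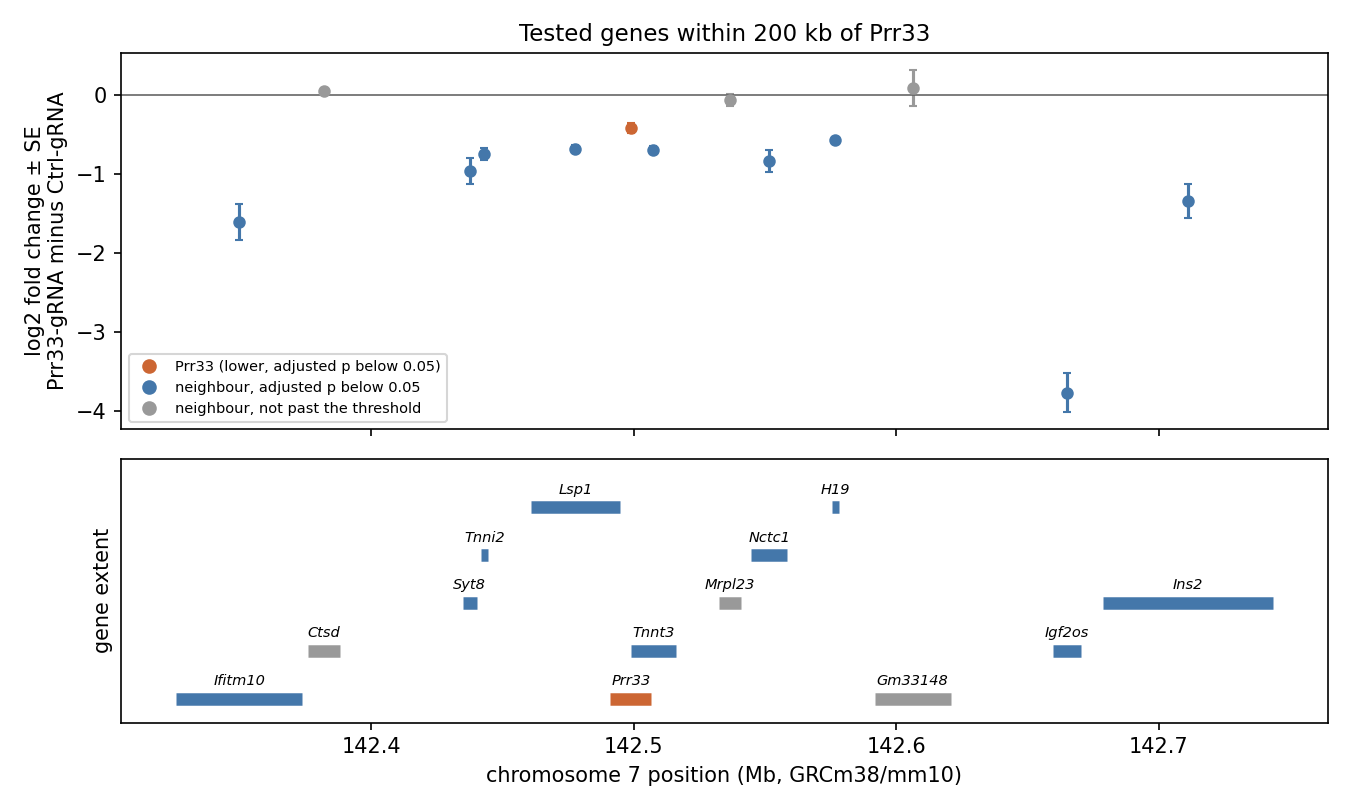
Tested genes within 200 kb of Prr33 on chromosome 7 (position in Mb on the horizontal axis). The upper panel gives each gene's log2 fold change, Prr33-gRNA minus Ctrl-gRNA, with bars of 1 SE from edgeR, and the lower panel its extent; 9 of the 12 neighbours and Prr33 itself lie below 0 past the threshold, and Ctsd, Mrpl23 and Gm33148 (grey) lie near 0.

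Across the transcriptome, 3740 genes were higher and 3899 lower in Prr33-gRNA among 14651 tested (edgeR, adjusted p below 0.05). Of the protein-coding genes among them 3478 were higher and 3414 lower. Long noncoding RNA genes (89 higher, 215 lower) and processed pseudogenes (63 higher, 132 lower) were more often lower, and the cause was not tested. Changes of at least 2-fold were more often falls, with 427 genes higher and 1166 lower. Among protein-coding genes averaging at least 5 CPM, with clone-named genes left out (1 of which, a Rik gene, rose further), the top rises were those of Xlr3a (log2 fold change 6.97, from 0.211 ± 0.148 to 27.4 ± 1.41 CPM), Mme (5.68), Gpr37 (5.34), Npepl1 (5.17), Tspyl5 (5.14) and Macroh2a2 (4.40). Mme encodes the membrane peptidase neprilysin, Gpr37 an orphan receptor and Macroh2a2 a histone variant. Glipr1 (3.47), Lpl (3.14), Npr3 (2.68) and Olfr805 (2.67) followed. Rftn1, for a lipid-raft protein, had 1688 counts over the Ctrl-gRNA libraries and 0 over the Prr33-gRNA libraries, at least 614-fold lower against a floor of 3 counts over the group. Oas1g went from 1145 counts to 0, at least 416-fold lower. Itpkb, an inositol phosphate kinase, went from 630 counts to 2, a ratio of 343 with a 95% counting interval of 94.7 to 2842. Rsad2, Trim30a and Cmpk2, which belong to the interferon-induced genes, had log2 fold changes of -8.53, -8.32 and -8.05, and Usp11, Ly6c1 and Krba1 of -7.56, -7.11 and -6.82. Trim34a, also interferon-induced, had 213, 147 and 242 counts in Ctrl-gRNA and 0, 0 and 5 in Prr33-gRNA, so its log2 fold change of -6.93 rests on Prr33-gRNA replicate 3, and the fitted value without that library was -10.68. The value for Tspyl5 was 6.43 without Ctrl-gRNA replicate 2, that for Ly6c1 -7.89 without Prr33-gRNA replicate 2, and that for Krba1 -7.50 without Prr33-gRNA replicate 1. Xlr3a, Oas1g, Ly6c1 and Trim34a belong to families of similar copies, so their values may hold reads of relatives. The groups did not overlap for 57.9% of tested genes, where chance gives 10%. Scaling by library size alone turned the split into 4999 higher and 3103 lower (61.7% higher), so the near-even split above depends on the scaling.

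The transcription factors that drive myogenesis moved in both directions. Of 18 tested members of the fixed list, 7 rose and 9 fell. Myod1, which commits cells to the muscle lineage, fell from 75.7 ± 1.99 to 25.1 ± 1.83 CPM (log2 fold change -1.59, edgeR adjusted p = 2.28e-20). Myog, which drives terminal differentiation, fell from 1186 ± 86.2 to 384 ± 23.0 CPM (-1.63, edgeR adjusted p = 7.83e-19). Tead4 fell from 143 ± 8.05 to 73.8 ± 2.82 CPM (-0.95). Myf5, which was listed with genes of undifferentiated myoblasts, rose from 76.5 ± 0.627 to 153 ± 7.75 CPM, and Mef2c rose by 0.34. Log2 fold changes of the members of the transcription factor list ran from -1.63 to 1.99. The list as a whole did not pass (camera adjusted p = 0.446). For this and the lists that follow, the counts adjusted over the list alone were the same as those over all genes unless given.

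Muscle structural genes were mostly lower. In the thick filament and M-band list 21 of 26 tested genes fell and 4 rose (camera adjusted p = 1.67e-05; adjusted p = 0.263 with an estimated correlation). Myh3, the embryonic myosin heavy chain, fell from 12684 ± 68.7 to 5282 ± 183 CPM (-1.26), and Mybph fell from 2416 ± 33.1 to 1021 ± 27.9 CPM (-1.24). The slow myosin gene Myh7, which lies on chromosome 14, fell from 227 ± 10.6 to 13.3 ± 1.18 CPM (-4.09), whereas Myh4, an adult fast myosin, rose from 34.2 ± 2.96 to 179 ± 5.31 CPM (2.38). In the thin filament and Z-disc list 30 of 36 fell and 3 rose (camera adjusted p = 2.65e-09; adjusted p = 0.263 with an estimated correlation). Cardiac alpha-actin Actc1 fell from 3295 ± 43.4 to 499 ± 14.8 CPM (-2.72), Csrp3 and Xirp2 fell (log2 fold changes of -2.40 and -1.43), and Tnnc1, on chromosome 14, fell from 1139 ± 15.1 to 476 ± 20.2 CPM. Skeletal alpha-actin Acta1 changed less, from 9885 ± 341 to 7359 ± 160 CPM (-0.43). The 3 that rose, Nebl (1.20), Actn2 (0.33) and Tpm1 (0.21), were picked out after their values were seen.

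Genes of excitation-contraction coupling and of the dystrophin complex also fell. In the former list 19 of 27 fell and 5 rose (camera adjusted p = 0.00427; adjusted p = 0.368 with an estimated correlation). Casq1, the calcium buffer of the fast-fibre sarcoplasmic reticulum, fell from 139 ± 12 to 16.4 ± 1.71 CPM (-3.09). Jph2, Casq2 and the calcium channel gene Cacna1s fell (log2 fold changes of -1.21, -0.75 and -0.57). In the dystrophin complex and costamere list 16 of 21 fell and 3 rose (camera adjusted p = 0.00133; adjusted p = 0.263 with an estimated correlation). Sgca, for a sarcoglycan, fell from 26.2 ± 2.62 to 3.39 ± 0.416 CPM (-2.95). Vcl, on chromosome 14, fell from 602 ± 11.8 to 301 ± 1.16 CPM. Among 30 tested genes for myoblast fusion 8 rose and 17 fell (9 and 17 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.136). Of the 2 muscle-specific fusogens, Mymx fell from 104 ± 6.91 to 43.9 ± 4.39 CPM (-1.24), and Mymk fell from 868 ± 23.6 to 736 ± 32.5 CPM (-0.24). Cav3 fell by 1.32, Bin3, on chromosome 14, fell by 1.25, and Neo1 rose by 0.69.

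**Figure D2:**
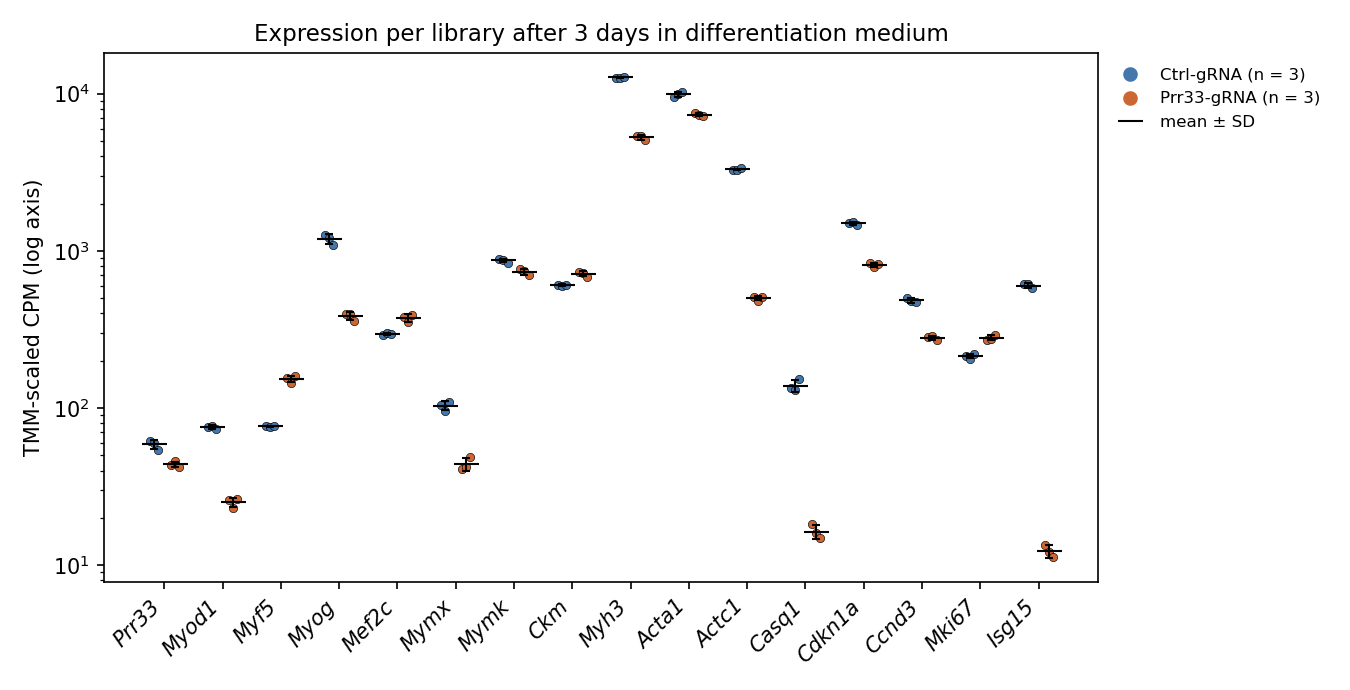
TMM-scaled CPM (log axis) of 16 named genes, 1 point per library, with the mean and SD of the 3 libraries of each group. Myog sits at 1186 ± 86.2 CPM in Ctrl-gRNA and 384 ± 23.0 CPM in Prr33-gRNA, Casq1 at 139 ± 12 and 16.4 ± 1.71 CPM, and Myf5 and Mki67 are higher in Prr33-gRNA.

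Proliferation genes were mostly higher and genes of cell cycle exit mostly lower. Of 39 proliferation genes 28 rose and 1 fell (29 and 2 adjusted over the list alone; camera adjusted p = 3.07e-06; adjusted p = 0.368 with an estimated correlation), with a median log2 fold change of 0.33. The number that fell was 2 without Prr33-gRNA replicate 2, in limma-voom, without a low-count filter and with protein-coding genes alone. Mki67, a marker of cycling cells, rose from 214 ± 7.09 to 280 ± 9.49 CPM (0.39). Cdc6, Cdc20 and Rrm1 rose by 0.97, 0.60 and 0.42, and the replication helicase gene Mcm6 fell by 0.77. Of 16 genes of cell cycle exit 12 fell and 2 rose (camera adjusted p = 0.00276; adjusted p = 0.263 with an estimated correlation). Cdkn1a, the inhibitor p21 that is induced as myoblasts stop dividing, fell from 1503 ± 32.6 to 814 ± 26.1 CPM (-0.88). Gadd45a, Gadd45g and Ccnd3 fell (log2 fold changes of -1.79, -1.02 and -0.79).

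Interferon-induced genes were lower throughout. Each of the 35 list members was tested and each fell, with a median log2 fold change of -3.69 (camera adjusted p = 2.16e-24; adjusted p = 0.263 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein, fell from 602 ± 19.4 to 12.3 ± 1.15 CPM (-5.62). The oligoadenylate synthetase family genes Oasl2 and Oas2 fell from 560 ± 20.7 to 26.8 ± 0.897 CPM and from 175 ± 7.14 to 4.76 ± 0.140 CPM. Bst2 fell from 753 ± 18.3 to 72.1 ± 3.71 CPM (-3.39). In the list of inflammation and chemokine genes 12 of 20 fell and 5 rose, and the list did not pass (camera adjusted p = 0.0940). Ccl5, Cxcl12 and Csf1 in it fell (log2 fold changes of -2.44, -3.62 and -0.85), and Ccl5 is also a member of the interferon list.

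Extracellular matrix genes split. Of 44 tested, 30 fell and 11 rose (camera adjusted p = 0.00126; adjusted p = 0.407 with an estimated correlation). The collagen gene Col1a1 fell from 179 ± 12.4 to 9.33 ± 0.949 CPM (-4.26), and Vcan and Fbn1 fell (log2 fold changes of -2.51 and -1.84), whereas Thbs1 rose from 858 ± 32.6 to 1902 ± 58.2 CPM (1.15). Among 10 tested markers of fibroblasts and mesenchymal progenitors 6 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.00480; adjusted p = 0.263 with an estimated correlation). Falls and rises numbered 5 and 2 without Ctrl-gRNA replicate 1, 6 and 0 without Ctrl-gRNA replicate 3, 7 and 0 without Prr33-gRNA replicate 2, 6 and 2 under library-size scaling, and 5 and 0 on either FPKM scale. Ly6a, the surface antigen Sca-1, fell from 464 ± 16.3 to 4.76 ± 0.405 CPM (-6.60), and Pdgfrb and Islr fell (log2 fold changes of -2.56 and -0.71).

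Among metabolic lists, 16 of 19 glycolysis genes fell and 0 rose (camera adjusted p = 1.99e-04; adjusted p = 0.368 with an estimated correlation). Pfkfb3, Pfkp, Pfkl and the glucose transporter gene Slc2a1 fell (log2 fold changes of -1.56, -1.28, -1.15 and -0.83). Of 42 cytosolic ribosomal protein genes 22 fell and 1 rose, with a median of -0.15 (camera adjusted p = 0.00480; adjusted p = 0.552 with an estimated correlation). Under library-size scaling 15 fell and 6 rose, with a median of -0.06, and the call was lost (camera adjusted p = 0.0586). Falls and rises numbered 21 and 0 without Ctrl-gRNA replicate 2, 23 and 3 without Ctrl-gRNA replicate 3, 19 and 2 without Prr33-gRNA replicate 1, and 21 and 2 without a low-count filter. The falls of Rps24 (-0.93) and Rpl15 (-1.30), both on chromosome 14, exceeded those of Rpl10a (-0.35) and Rps16 (-0.35). Of 23 cholesterol synthesis genes 14 rose and 5 fell (camera adjusted p = 0.0428; adjusted p = 0.263 with an estimated correlation). Idi1 and Sc5d rose by 0.65 and 0.49, and Srebf2 and Fdft1, the latter on chromosome 14, fell (log2 fold changes of -0.33 and -0.82). The cholesterol call was lost without Ctrl-gRNA replicate 3 (camera adjusted p = 0.0830) and without Prr33-gRNA replicate 2 (camera adjusted p = 0.0687). It was also lost with a stricter filter, with protein-coding genes alone and under library-size scaling (camera adjusted p = 0.0523, 0.0566 and 0.0576).

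**Figure D3:**
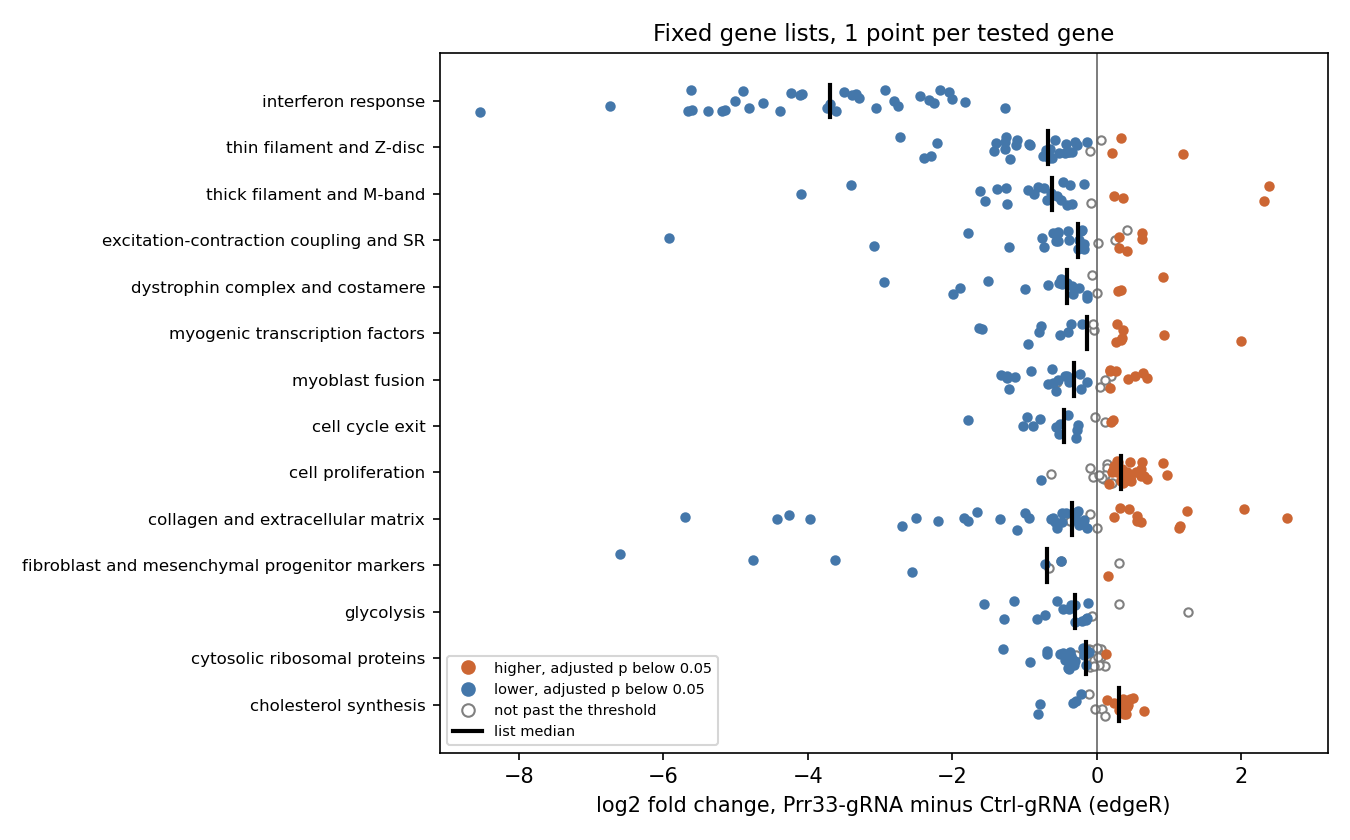
log2 fold change (horizontal axis, Prr33-gRNA minus Ctrl-gRNA, edgeR) of each tested member of 14 fixed gene lists, with 3 libraries per group. Filled points passed the adjusted p threshold, and vertical bars are list medians; the interferon response has its median at -3.69 and each of its 35 points below 0, and genes with 0 counts in a group are drawn at the bound set by 3 counts.

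Genes on chromosome 14 were lower along its whole tested length. Of its 400 tested protein-coding genes 361 fell and 10 rose, with a median log2 fold change of -0.90 and quartiles of -1.15 and -0.66. The 11650 tested protein-coding genes on the other autosomes and the X had a median of 0.02 and quartiles of -0.25 and 0.24. Chromosome 14 took 3.01% ± 0.00641 of the counts in Ctrl-gRNA (SD, n = 3) and 1.80% ± 0.00457 in Prr33-gRNA (SD, n = 3). With chromosome 14 left out, a step added after the values were seen, 3520 genes were higher and 3650 lower. The lists then gave 20 of 25 thick filament genes lower, 26 of 32 thin filament genes, 14 of 19 dystrophin complex genes, 34 of 34 interferon genes and 28 of 41 matrix genes. Each of the 12 lists past the threshold still passed (camera, preset correlation). With an estimated correlation, which was run with chromosome 14 kept, 0 of 33 lists passed (lowest adjusted p 0.263; 4 at an unadjusted p below 0.05), while fry passed 32.

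**Figure D4:**
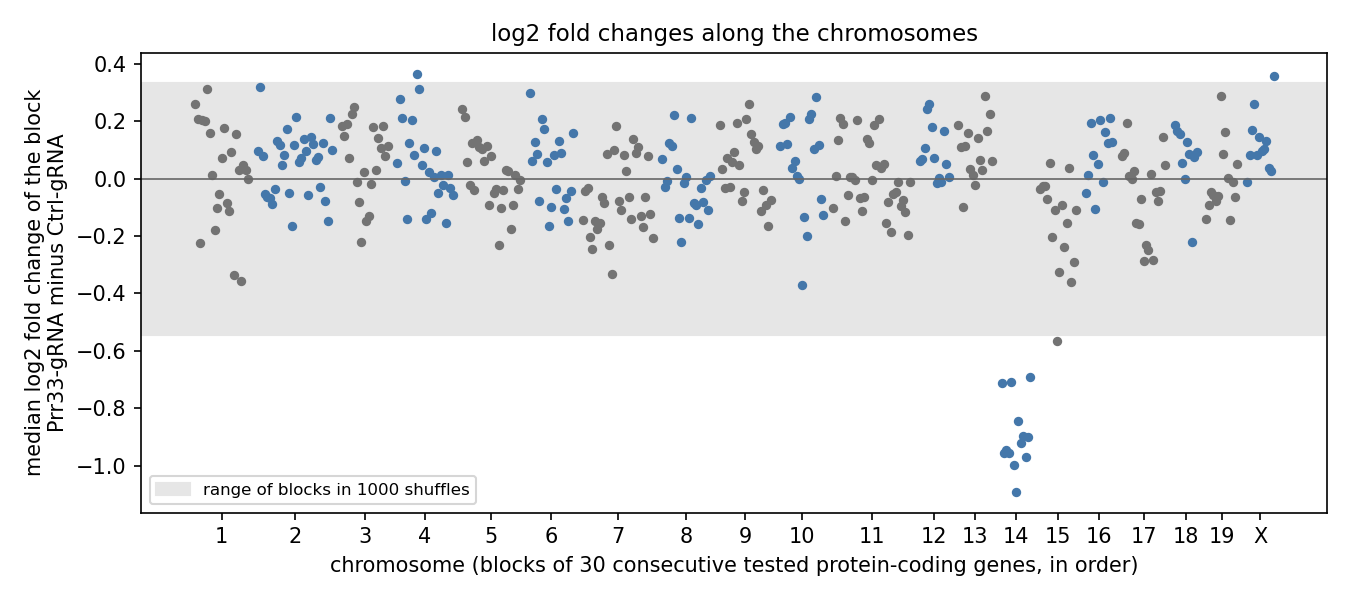
Median log2 fold change (vertical axis, Prr33-gRNA minus Ctrl-gRNA) of blocks of 30 consecutive tested protein-coding genes, ordered along chromosomes 1 to 19 and X. The grey band is the range of blocks after 1000 shuffles of gene order, -0.55 to 0.33. The 13 blocks of chromosome 14 and 1 of chromosome 15 (-0.56) lie below it, and 1 block each of chromosome 4 (0.37) and X (0.36) lie above it.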

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

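Library-size scaling, the removal of rows without an Ensembl ID or on patch scaffolds, and the removal of chromosome 14 were chosen after the data were seen. Prr33 stayed lower past the threshold in each of the 18 alternative fits, with log2 fold changes from -0.47 to -0.33, and 6 to 9 of its neighbours were lower, 6 being the count when noncoding genes were left out. Across the fits other than library-size scaling, 3260 to 3811 genes were higher and 3484 to 3978 lower, and no gene called in both a fit and the main comparison changed sign. Requiring an absolute log2 fold change of at least 1 left 427 higher and 1166 lower, since it drops smaller changes. Samples that share a replicate number did not deviate together (correlations of -0.01, -0.01 and 0.02), so the numbers do not pair the libraries; with a replicate block 3811 genes were higher and 3975 lower, sharing 3713 and 3873 with the main fit, and cholesterol synthesis gave an adjusted p of 0.0525. Of 2897 values for 162 named genes, 22 changed side of the threshold and 0 changed direction past it; Sox9, Kcnq1ot1, Gas5, Map2, Xist, Ctsd and Vwf were those that changed. The rest concerns gene lists, as adjusted p-values, and the cause was not tested except where the setting itself gives it. Cholesterol synthesis lost its call with the stricter filter (0.0523), with protein-coding genes only (0.0566) and under library-size scaling (0.0576), and ranged from 0.0320 to 0.0830 when single libraries were left out. Mitochondrially encoded transcripts, not called in the main test, were called without a low-count filter (0.0470) and with protein-coding genes only (0.00684), which leaves out the mitochondrial rRNAs that fell; leaving out single libraries gave 0.0231 to 0.146. The unfolded protein response was called without a filter (0.0400). Under library-size scaling, ribosomal proteins lost their call (0.0586) and inflammation gained one (0.0398). With an estimated correlation, 0 of 33 lists passed against 12 with the preset one, and 4 had an unadjusted p below 0.05, the lowest being 0.0136. The values were 0.263 for cell cycle exit, cholesterol synthesis, the dystrophin complex, fibroblast markers, the interferon response, the thick filament and the thin filament, 0.368 for proliferation, excitation-contraction coupling and glycolysis, 0.407 for matrix and 0.552 for ribosomal proteins. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, passed 32 lists. It added Notch targets (0.0245), TGF-beta and BMP targets (0.00115), YAP and SRF targets (2.55e-04), apoptosis and autophagy (0.00390), bone markers (0.00390), endothelial markers (0.00133), inflammation (2.14e-04), insulin-like growth factor signalling (0.0153), muscle energy metabolism (0.0181), fusion (1.95e-04), myogenic transcription factors (0.00506), the RNA quality list (0.00206), oxidative phosphorylation (0.0222), the p53 response (0.00189), smooth muscle markers (7.20e-05), undifferentiated myoblast genes (9.41e-04) and the unfolded protein response (4.98e-04) as lower, and adipocyte (0.00267) and neuronal markers (0.0271) as higher. The neuromuscular junction list turned from higher, uncalled, in camera to lower in fry (6.81e-04). Depth was not varied. At these library sizes the simulation recovered 25 of 50 genes at 1.25-fold and 39 of 50 at 2-fold. The simulation changed far fewer genes than the 7639 called here. Its adjusted p threshold was therefore harder to pass, and its recovery does not measure that of the real comparison.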

Other observations

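The tests of chromosome 14 by library, of blocks without chromosome 14 and of the Prr33 locus, and the values under library-size scaling, were chosen after the result was seen; the other block tests and the leukocyte, RLE and grouping tests were not. Other fixed lists held changes in both directions without passing camera. Of 20 genes of undifferentiated myoblasts 7 rose and 9 fell (camera adjusted p = 0.426); Cd34, a surface marker of progenitors, fell from 35.8 ± 0.784 to 0.985 ± 0.187 CPM (SD, n = 3), Notch3 and Notch1 each had a log2 fold change of -1.40, and Pax7 fell from 1.78 ± 0.357 to 0.680 ± 0.213 CPM. Of 14 neuromuscular junction genes 5 rose and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.957). Agrn, the gene for agrin, fell from 628 ± 11.8 to 110 ± 4.01 CPM, while Lrp4, Musk and Chrnd rose by 0.61, 0.56 and 0.40. Of 24 muscle energy genes 6 rose and 14 fell (7 and 14 adjusted over the list alone; camera adjusted p = 0.410); muscle creatine kinase Ckm rose from 606 ± 5.38 to 713 ± 26.1 CPM. Of 13 mitochondrially encoded transcripts 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.101): mt-Cytb rose by 0.67 and the ribosomal RNA mt-Rnr1 had -2.47. In the RNA quality list 1 of 6 rose and 3 fell (camera adjusted p = 0.438), with the nuclear RNA Neat1 at 874 ± 68.7 against 220 ± 9.59 CPM. Under library-size scaling the muscle energy list had 7 higher and 9 lower (6 and 9 in DESeq2), the neuromuscular junction list 6 and 2, and the RNA quality list 1 and 1. The RNA quality list had 0 and 2 in DESeq2 and without Ctrl-gRNA replicate 1, 0 and 3 without Prr33-gRNA replicate 1, and 0 and 1 on either FPKM scale, so its split is not settled. With protein-coding genes alone, 8 mitochondrially encoded transcripts were higher and 0 lower.

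Signalling lists were mixed as well, none passing camera. TGF-beta and BMP targets had 7 of 21 higher and 11 lower (7 and 13 adjusted over the list alone; adjusted p = 0.216), among them the myostatin antagonist Fst at -1.34. YAP and SRF targets had 6 of 24 higher and 12 lower (6 and 13 adjusted over the list alone; adjusted p = 0.0985), with Ccn2 and Ankrd1 at -1.65 and -0.91 and Cavin2 at 1.42. Insulin-like growth factor signalling had 5 of 18 higher and 10 lower (adjusted p = 0.426; median -0.20 and mean 0.01 differ in sign), Notch targets 1 of 7 higher and 1 lower (0.779), the p53 response 5 of 20 higher and 8 lower (6 and 9 adjusted over the list alone; 0.414), the unfolded protein response 3 of 23 higher and 12 lower (0.0861), with Atf3 at -2.21, apoptosis and autophagy 7 of 26 higher and 12 lower (7 and 13 adjusted over the list alone; 0.331), and oxidative phosphorylation 5 of 37 higher and 14 lower (5 and 15 adjusted over the list alone; 0.186). Among markers of other cell types, smooth muscle genes had 2 of 11 higher and 5 lower (0.141; Actg2 at -3.82), adipocyte genes 4 of 10 higher and 4 lower (0.633; Lpl at 3.14, Cebpd at -1.61), bone and cartilage genes 1 of 7 higher and 2 lower (0.693; Bglap2 at -3.81), endothelial genes 0 of 5 higher and 1 lower (0.131; Flt1 at -2.52) and neuronal genes 4 of 6 higher and 1 lower (0.413; Tubb3 at -2.27). Of 16 leukocyte markers 2 were expressed enough to test, Cd14 and Cd68, and 0 were called by edgeR. Leaving out single libraries moved some of these counts: oxidative phosphorylation had 2 higher and 12 lower without Ctrl-gRNA replicate 1 or 2, 2 and 13 without Prr33-gRNA replicate 1, and 3 and 11 without Prr33-gRNA replicate 3. Without Prr33-gRNA replicate 3 the unfolded protein response had 5 and 11, smooth muscle genes 4 and 5, and bone and cartilage genes 1 and 1; endothelial genes had 0 and 2 without Ctrl-gRNA replicate 3 or Prr33-gRNA replicate 2, and in limma-voom. DESeq2 gave 4 and 10 for apoptosis and autophagy and 1 and 1 for bone and cartilage genes, and log2(FPKM + 1) gave 3 and 2 for neuronal genes. Under library-size scaling insulin-like growth factor signalling had 7 and 7, the unfolded protein response 7 and 10, Notch targets 2 and 1, bone and cartilage genes 1 and 1, and oxidative phosphorylation 9 and 8. List medians of log2 fold change then turned positive for the neuromuscular junction (-0.07 to 0.02), Notch targets (-0.05 to 0.04), the p53 response (-0.06 to 0.03) and oxidative phosphorylation (-0.08 to 0.01), so these lists have no direction apart from the scaling. At the extremes, 12 genes with at least 5 CPM in Ctrl-gRNA had at most 3 counts over the Prr33-gRNA libraries, and 3 genes showed the opposite.

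The real grouping gave 7639 changed genes and 12 lists past the threshold. The highest of the other 9 of 10 splits of the 6 libraries gave 0 genes and 8 lists (edgeR and camera), and 1 split, the real one, gave as many of each. With 10 splits the share cannot fall below 0.05. Each of the other splits mixes libraries of both groups. The group difference then enters the spread within each side, and part of it the difference between sides. Their counts of genes and lists therefore do not measure what chance gives.

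The first pattern is the fall of all 35 interferon response genes. Leukocytes in the control cultures are argued against, since the most abundant of their 16 markers, Cd14, reached 4.55 CPM and 0 exceeded 50 CPM. Scaling between libraries is argued against too, since the list median was -3.60 or lower under each of TMM, RLE and library-size scaling. The source stays open: the Prr33 guide, or a difference between derived lines, such as an interferon response raised in the control line. The labels do not name more than 1 line per guide, so these sources cannot be told apart.

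The second pattern is that neighbouring genes share log2 fold changes, above all on chromosome 14, although without that chromosome the spread of block medians was still 1.83 times the shuffled one (0 of 1000 shuffles as large). A chance order of genes is argued against. In the shuffles, 0 of 1000 gave block medians as spread (permutation p = 0.001, the smallest they can give). The spread stayed 2.33 times the shuffled one without genes over 1 in absolute log2 fold change. It was 2.80 times the shuffled one after GC content and gene length were taken out. Both tests took all chromosomes together, so the blocks of chromosome 14 alone may have kept the spread high. They argue against clusters of strongly changed genes, or GC content and gene length, as the only source of the pattern. For the spread left without chromosome 14 they were not run, so there these explanations stay open. A difference in chromosome copy number remains a candidate explanation for chromosome 14: 13 adjacent blocks, from 6735685 to 121380011 on chromosome 14, shifted together, to a median level of 0.537 of control. Each library carried the shift, at 3.00% to 3.01% of counts in Ctrl-gRNA and 1.79% to 1.80% in Prr33-gRNA, which is consistent with loss of copies in the cells the Prr33-gRNA libraries share, or a gain in those of the control, as a hypothesis that DNA from both lines would test. Prr33 lies on chromosome 7, so falls of chromosome 14 genes such as Tnnc1, Vcl and Rpl15 may reflect that shift rather than the guide's target.

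The third pattern is that Prr33 and genes next to it were lower. The block of 30 genes that spans them (141447370 to 143756985 on chromosome 7) had a median of -0.21. In it 14 genes passed the threshold as lower and 3 as higher. Its median lies inside the range of shuffled blocks, -0.55 to 0.33. That range holds the extremes of 1000 shuffles, with chromosome 14 genes among those shuffled. Lying inside it therefore does not show whether the region as a whole was shifted. Exonic reads shared with Tnnt3 or Lsp1 stay open as a source: the overlapping share of Prr33's exonic bases was 0 in GENCODE M21, but the counted gene model, at 2514 bases against 2348, is another one, and reads from unspliced RNA stay untested. A fall of sarcomere genes in general stays open too: 67.7% of the 62 tested sarcomere genes fell further than Prr33, but their 5th to 95th percentile, -2.39 to 0.36, holds 81.8% of all tested genes, so this decides nothing. An effect of the edit on the transcript stays open as well, and the lower Prr33 level alone does not show how much protein was lost.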
